A study of Homo sapiens with 16 samples.

How the data were processed

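The data are ChIP-seq peak lists of HNF4A, KLF5, MYC, RAD21, CTCF and histone H3 in LoVo colon adenocarcinoma cells held in early S phase or in M phase, 1 library per target and phase, with rabbit IgG as the control for all targets but CTCF and goat IgG as the control for CTCF. Each immunoprecipitation used 5 µg of antibody, per the labels. Targets and phases were taken from the sample titles. The design text of the series names an siRNA against RAD21, but no label of these 16 samples carries such a treatment, and none was assumed.

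Per the submitters' processing notes, reads were processed with CASAVA 1.4, aligned with BWA to the human build hg18 (version 18) and passed to MACS 1.4; the file headers give MACS 1.4.0rc2. Per the file headers, peaks were called for each target and phase on merged alignments against the IgG library, with a p-value cutoff of 1e-05, a band width of 300 bp, a model fold range of 2 to 6, tags of 32 or 33 bases, an effective genome size of 2750000000 bp and at most 1 tag kept at a position. How many sequencing runs were merged is not given in the sources used here. Per the file headers, the S-phase CTCF tags and their goat IgG control came from a differently named set of alignments than the S-phase rabbit libraries, and the labels do not say whether these were the same cultures. The deposited tag counts per peak are whole numbers without normalization. The deposited score is -10 times the log10 of the MACS p-value, so that the cutoff is a score of 50. The deposited fold enrichment is the ratio of tags over the local background that MACS models from the control. The deposited FDR is a percent that MACS derives by exchanging ChIP and control, and positions are hg18 coordinates.

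The labels speak of peaks with an FDR under 5%. The lists were tested against this: the number given in the labels equalled the full length of the list for all 11 lists with such a number, and peaks with an FDR of 5% or more were present in 8 of the 12 lists. All listed peaks were used. The labels give no peak number for M-phase KLF5 and give 2118 for the M-phase rabbit IgG control, which is the length of the M-phase KLF5 list.

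Lists were compared by overlap with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. An S-phase peak was called kept if an M-phase peak of the same target overlapped it by at least 1 bp. Shares have exact Clopper-Pearson 95% intervals and differences of shares that were not standardised have Newcombe intervals. Standardised differences have normal 95% intervals from the binomial variances within the groups of score. All are over peaks. With 1 library per group no test across samples exists, and no p-value was computed. Chance was estimated from 1000 circular shifts of a list along each chromosome (100 between the factors), with seed 1. Tags per 1000000 library tags are the deposited tag counts divided by the filtered tags of the library that the headers state. Differences standardised for strength compare kept shares within 10 equal groups of the S-phase score, weighted by the smaller class. Clusters chain peaks of the 5 proteins with gaps of at most 1000 bp. Scores and fold enrichments were used to rank, divide or describe the peaks of 1 list. Exceptions were Spearman's rho between S-phase and M-phase scores at kept peaks and the score minimum of 100, applied to the lists of both phases.

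Named regions followed a rule fixed before the data were examined: for each protein, the 3 S-phase peaks of highest fold enrichment that were kept, the 3 with no M-phase peak of that protein within 1000 bp, and the 3 M-phase peaks with no S-phase peak within 1000 bp, on chromosomes 1 to 22 and X and away from H3 peaks. The rule also takes the 5 S-phase clusters with the most proteins and peaks that contain an M-phase factor peak and the 5 that contain none. A part of these is named. Gene groups had been fixed too, but no hg18 annotation was used here, so no peak was assigned to a gene. Alternatives covered the overlap rule, score and FDR minimums, peaks at H3 peaks, the number and ranking of strongest peaks, gaps of 500 and 3000 bp and another chance level.

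The overlap and standardisation steps were tested on simulated data. On lists made from the 27122 S-phase RAD21 peaks, kept shares were recovered within 0.0590 percentage points. A standardised difference of 0.611 points was found where strength alone set the kept share, and 20.0 points where 20 had been put in. Strength in these simulations was the observed score itself, so noise in the score was not covered.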

Results

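Binding of 5 nuclear proteins was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in LoVo cells, an established human colon adenocarcinoma line, held at 2 points of the cell cycle. Cells in early S phase, when DNA is copied, came from a double block with 2 mM thymidine: 12 h in thymidine, 8 h of release and another 12 h in thymidine. Cells in M phase, when chromosomes are condensed and separated, came from a single 12 h thymidine block followed by 8 h in 200 ng/ml nocodazole, which stops the assembly of the mitotic spindle. HNF4A is a nuclear receptor of intestinal and liver epithelium, KLF5 a zinc-finger factor of proliferating gut epithelium, and MYC a helix-loop-helix factor that drives growth. RAD21 is a subunit of cohesin, the ring-shaped complex that holds sister chromatids together, and CTCF is the zinc-finger protein at whose sites cohesin gathers. An antibody to histone H3 served as a chromatin control, and rabbit and goat IgG as background controls. The title of the series places the binding of transcription factors in clusters around cohesin sites, and the lists of the 2 phases allow such sites to be followed from S phase into mitosis.

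Of the 16 libraries, 12 had a peak list, 1 for each target in each phase, and the other 4 were IgG controls. There was no replicate of any target in either phase, so no difference between the phases could be set against a spread between samples. Intervals below are 95% intervals over peaks, Clopper-Pearson for shares, and cover counting error only. After removal of repeated tags, the ChIP libraries held between 7362169 tags (KLF5 in M phase) and 16813394 tags (HNF4A in M phase). The rabbit IgG controls held 10753369 tags in S phase and 6875106 in M phase, and the goat IgG controls 3658103 and 4222390.

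The lists of the 3 transcription factors were much shorter in M phase than in S phase. The full RAD21 and CTCF lists were only slightly shorter. HNF4A had 15437 peaks in S phase and 2413 in M phase, a ratio of 6.40. MYC had 11941 and 1974 peaks, a ratio of 6.05, and KLF5 had 5928 and 2118 peaks, a ratio of 2.80. RAD21 had 27122 peaks in S phase and 22966 in M phase, a ratio of 1.18, and CTCF had 28474 and 24391, a ratio of 1.17. The M-phase RAD21 and CTCF libraries held 2.19 and 1.89 times the filtered tags of S phase, the largest gains in depth of any target. The H3 list, the chromatin control, shortened as much as those of HNF4A and MYC, from 3290 peaks in S phase to 542 in M phase, a ratio of 6.07. The M-phase libraries of HNF4A and MYC were the deeper ones, with 1.38 and 1.65 times the filtered tags of the S-phase libraries, as was that of H3 with 1.10 times; the M-phase KLF5 library held only 0.712 times as many. The authors' false discovery rate (FDR) was 100% for 78.8% of M-phase HNF4A peaks, 77.3% of M-phase MYC peaks and 99.8% of M-phase H3 peaks. No M-phase HNF4A peak had an FDR below 5.88%. All listed peaks had passed the caller's cutoff, and this FDR comes from exchanging ChIP and control. The M-phase HNF4A, MYC, H3 and RAD21 libraries all held more tags than the 6875106 of their control. How this imbalance moved the FDR was not tested, so its values are given as deposited. Of the M-phase KLF5 peaks, 396 had an FDR under 5%. With an FDR under 5%, RAD21 had 27122 peaks in S phase and 14307 in M phase, and CTCF had 20190 and 8917. Both thus fell more at this limit than in the full lists.

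Few S-phase factor peaks were found again in M phase, but most RAD21 and CTCF peaks were. A peak was counted as kept when an M-phase peak of the same target overlapped it by at least 1 bp. Of the S-phase peaks, 12.3% were kept for HNF4A (1901 peaks, 95% interval 11.8 to 12.8%), 11.4% for KLF5 (676 peaks, 10.6 to 12.2%) and 12.6% for MYC (1500 peaks, 12.0 to 13.2%). RAD21 kept 69.7% of its S-phase peaks (18916 peaks, 69.2 to 70.3%) and CTCF 69.4% (19759 peaks, 68.9 to 69.9%). H3 kept 2.83% (93 peaks, 2.29 to 3.45%). When the M-phase lists were shifted along the chromosomes 1000 times, the mean share kept was 0.175% for HNF4A, 0.187% for KLF5 and 0.210% for MYC, and 1.60% for RAD21 and 2.05% for CTCF. The share was therefore far above chance for every target, H3 included, whose shifted lists gave 0.0372%. The length of the M-phase list limits these shares: for only as many strongest S-phase peaks as the M-phase list holds, 51.4% were kept for HNF4A, 22.8% for KLF5, 44.0% for MYC, 77.1% for RAD21 and 75.6% for CTCF. With a stricter overlap rule the shares were lower: with 50% of each peak shared, 6.68% of HNF4A, 6.12% of KLF5 and 9.60% of MYC peaks were kept, and 67.5% of RAD21 and 52.9% of CTCF peaks.

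Seen from M phase, HNF4A and MYC peaks lay mostly where S-phase cells already had one. An S-phase peak of the same factor was present at 79.9% of the M-phase HNF4A peaks (78.2 to 81.4%) and at 76.3% of the M-phase MYC peaks (74.4 to 78.2%), close to the 82.0% of RAD21 and 82.8% of CTCF. KLF5 stood apart: only 32.3% of its M-phase peaks (30.4 to 34.4%) met an S-phase KLF5 peak, against 0.524% in shifted lists. The labels give the length of this list to the M-phase rabbit IgG control and do not say whether the 2 libraries were exchanged. An exchange would touch every M-phase KLF5 value and also the M-phase HNF4A, MYC, RAD21 and H3 lists, which were called against that control. Of the 2118 M-phase KLF5 peaks, 1407 had no S-phase KLF5 peak within 1000 bp, against 478 HNF4A and 444 MYC peaks. Of these KLF5 peaks, 17.9% overlapped an S-phase peak of any of the 5 proteins, against 6.69% of such HNF4A and 20.3% of such MYC peaks.

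Strong S-phase sites were kept far more often than weak ones. Among the 1000 S-phase peaks of highest MACS score, RAD21 kept all 1000 (lower bound 99.6%) and CTCF 995 (99.5%, 98.8 to 99.8%). HNF4A kept 727 of its 1000 strongest (72.7%, 69.8 to 75.4%), MYC 587 (58.7%, 55.6 to 61.8%), KLF5 340 (34.0%, 31.1 to 37.0%) and H3 70 (7%, 5.50 to 8.76%). With 50% of each peak shared, the order of HNF4A and MYC turned, with 38.1% kept for HNF4A, 44.4% for MYC and 16.8% for KLF5. Against only the 500 strongest peaks of each M-phase list, too few to match all 1000, HNF4A kept 34.3%, MYC 31.9%, KLF5 21.5%, RAD21 32.2% and CTCF 30.7%. The strongest of 10 equal groups by S-phase score held 51.4% of all kept HNF4A peaks, 43.9% of kept MYC peaks and 38.0% of kept KLF5 peaks. In the weakest of these groups, HNF4A kept 0.583%, MYC 1.42% and KLF5 3.71%, whereas RAD21 kept 27.2% and CTCF 30.9%. The shares of all peaks depended on the M-phase threshold: with both lists restricted to an FDR under 5%, a restriction chosen after the data were seen, MYC kept 0.729% and KLF5 5.16% of their S-phase peaks, and RAD21 50.5% and CTCF 40.1%. HNF4A had no M-phase peak left under that restriction.

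**Figure D1:**
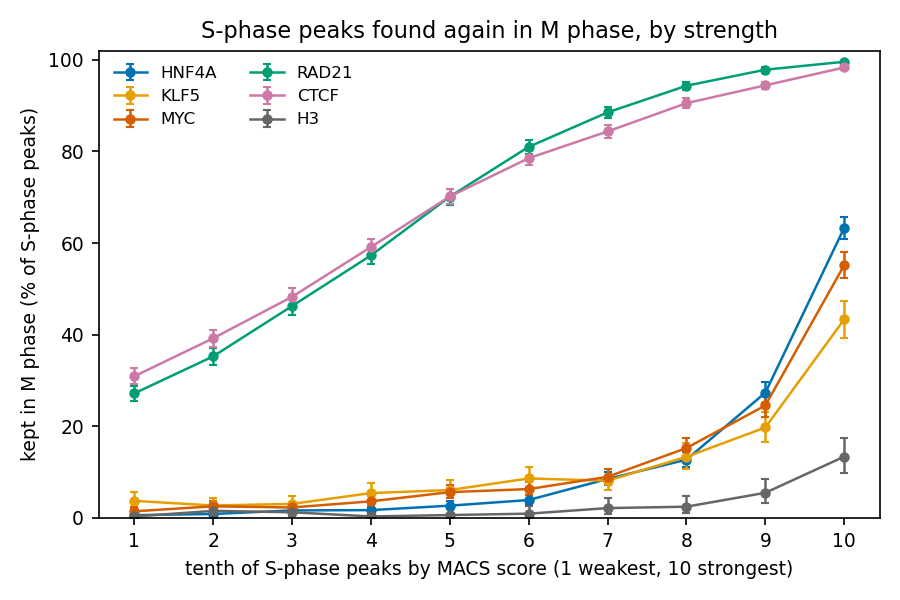
Share of S-phase peaks kept in M phase (vertical axis, percent) against 10 equal groups of S-phase peaks by MACS score, weakest to strongest (horizontal axis), for the 6 targets, with 95% Clopper-Pearson intervals as bars. RAD21 rises from 27.2% to 99.6% and CTCF from 30.9% to 98.3%, while HNF4A, MYC and KLF5 stay low over most groups and reach 63.3%, 55.2% and 43.3% in the strongest.

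Kept peaks of the 3 factors and of CTCF were narrower in M phase, and those of all 5 proteins held fewer tags for the size of the library. At the 1873 HNF4A sites with 1 peak in each phase, the median was 5.75 tags per 1000000 library tags in S phase over a median width of 1482 bp, and 1.55 in M phase over 780 bp. On the same scale MYC showed 7.11 tags over 1830 bp and 1.89 over 1154 bp at 1459 such sites. KLF5 had 4.54 tags over 1668 bp in S phase and 2.17 over 860 bp in M phase at 659 sites. RAD21 changed least, from 3.45 tags over 950 bp to 2.60 over 1090 bp at 18670 sites. CTCF went from 7.18 tags over 1476 bp to 2.40 over 900 bp at 19311 sites. Because the widths were called separately in each list, these sums move with the called width. The fragment size d in the file headers went the same way as the widths. From S to M phase it fell for HNF4A (240 to 176 bp), KLF5 (287 to 224), MYC (278 to 262) and CTCF (308 to 191). For RAD21 it rose from 213 to 226 bp. Whether it set the widths was not tested.

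Single sites show both outcomes. Positions are in the human genome build hg18, and fold enrichment, by which the sites are ordered, is the authors' value over IgG within each list. Tag counts at single sites are as deposited and not scaled to library size. Filtered tags, M over S phase, were 1.38 for HNF4A, 1.65 for MYC, 0.712 for KLF5, 2.19 for RAD21 and 1.89 for CTCF. The S-phase HNF4A peak of highest fold enrichment, on chromosome 10 from 135041132 to 135042555, held 243 tags at 103.72-fold in S phase together with KLF5 and MYC peaks, and its M-phase HNF4A peak held 68 tags with neither of the other factors. On chromosome 1 from 100207290 to 100209301, an HNF4A peak of 177 tags at 96.91-fold overlapped KLF5, MYC and RAD21 peaks in S phase, and in M phase only HNF4A was listed, with 40 tags. An HNF4A peak of 165 tags at 90.33-fold on chromosome 3 from 140063894 to 140065708 overlapped RAD21 in both phases. The HNF4A site of highest fold enrichment without an M-phase peak lay on chromosome 2 from 228967599 to 228968853, with 91 tags at 56.45-fold and no peak of the other 4 proteins in either phase. Next came sites on chromosome 20 from 47737414 to 47738969 with 85 tags and on chromosome 21 from 32757228 to 32758738 with 76 tags, both at 49.87-fold.

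For MYC, the leading kept site was on chromosome 2 from 202838569 to 202839772, where an S-phase peak of 112 tags at 80.41-fold lay with HNF4A and KLF5, and the M-phase MYC peak had 69 tags. A MYC site on chromosome 5 from 154113713 to 154115476, 143 tags at 71.94-fold, overlapped a CTCF peak in both phases. MYC peaks with no M-phase counterpart were led by chromosome 19 from 10077494 to 10078865 with 105 tags at 53.96-fold and by chromosome 8 from 101803334 to 101804616 with 57 tags at 50.55-fold, neither at a peak of another protein. KLF5 was kept on chromosome 5 from 138115941 to 138117004, where it had 82 tags at 57.02-fold in S phase and 44 tags in M phase, with an HNF4A peak in both phases. It was not listed in M phase on chromosome 21 from 46879441 to 46881133, where 65 tags at 36.13-fold overlapped HNF4A and MYC peaks in S phase. The kept KLF5 site on chromosome 1 from 1060551 to 1062669 held its M-phase peak, from 1061838 to 1062357, wholly inside it. It still counted as kept with summits within 100 bp, but not once 50% of each peak had to be shared or a score of at least 100 was required. The kept HNF4A site on chromosome 1 did not meet the 50% overlap either.

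Whether a cohesin site was found in mitosis went with the presence of CTCF. CTCF peaks covered 76.2% of the S-phase RAD21 peaks. Of these 20678 sites, 81.2% were kept in M phase (80.6 to 81.7%), against 33.0% of the 6444 RAD21 sites without CTCF (31.9 to 34.2%). With an FDR under 5%, a restriction chosen after the data were seen, the shares were 61.9% and 13.9% where only the M-phase RAD21 list was restricted, and 67.6% and 22.3% where all lists were. Over all listed peaks, 81.2% against 33.0%, the difference was 48.1 percentage points (Newcombe 95% interval 46.9 to 49.4). Sites with a peak of HNF4A, KLF5 or MYC were kept less often than sites without: 24.96% against 36.7% where CTCF was absent, and 72.2% against 82.5% where it was present. Without CTCF the share kept was 26.6% at sites with HNF4A, 26.8% with KLF5 and 25.7% with MYC.

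RAD21 sites without CTCF were also weaker, with a median MACS score of 78.1 against 175 at sites with CTCF. When the sites were divided into 3 equal groups by score, the difference remained in each: 53.9% against 21.0% kept in the weakest group, 80.0% against 52.0% in the middle and 96.9% against 90.2% in the strongest. Standardised over 10 groups of the score, an analysis added after the data were seen, the difference was 27.4 points (25.9 to 28.9). The difference between sites with and without a factor shrank in the same way, to -4.58 points (-6.79 to -2.38) without CTCF and -7.66 points (-9.22 to -6.10) with CTCF. Of the S-phase CTCF peaks, 79.5% were kept with RAD21 and 44.1% without, a difference of 35.4 points (34.2 to 36.6). The latter were weaker, with a median score of 88.3 against 202, and the standardised difference was 18.7 points (17.3 to 20.01).

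**Figure D2:**
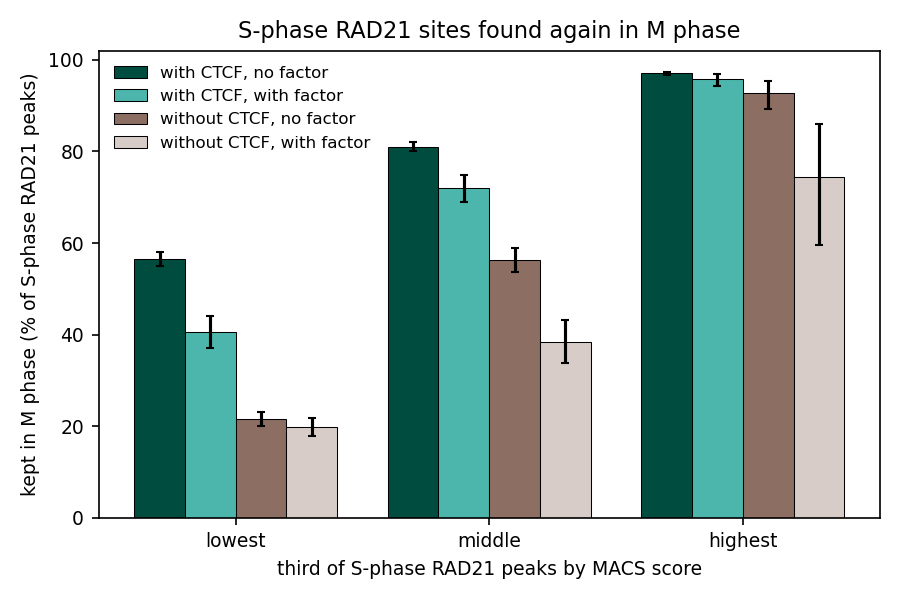
Share of S-phase RAD21 peaks kept in M phase (vertical axis, percent) in 3 equal groups of the S-phase MACS score (horizontal axis), with bars for sites with or without a CTCF peak and with or without a peak of HNF4A, KLF5 or MYC, and 95% Clopper-Pearson intervals. In the middle group the bars fall from 81.1% (CTCF, no factor) to 38.4% (factor, no CTCF).

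The leading kept RAD21 site lay on chromosome 19 from 46902070 to 46903809. It held 154 tags at 108.19-fold in S phase with CTCF, HNF4A, KLF5 and MYC, and in M phase 162 RAD21 tags with CTCF alone. These counts are not scaled, and the M-phase RAD21 library held 2.19 times the filtered tags. Similar counts are thus a smaller share of the M-phase library. On chromosome 12 from 76842911 to 76844378, RAD21 had 150 tags in S phase with CTCF and HNF4A and 164 tags in M phase with CTCF alone. On chromosome 17 from 45632411 to 45633625, 145 S-phase tags lay with CTCF and KLF5, and 137 M-phase tags with CTCF alone. Each of the 3 RAD21 sites of highest fold enrichment without an M-phase RAD21 peak overlapped CTCF in S phase, led by chromosome 11 from 100804479 to 100805445 with 36 tags at 37.86-fold. The CTCF site of highest fold enrichment, on chromosome 16 from 56239320 to 56241658, had 311 tags at 250.59-fold in S phase with MYC and RAD21, and 184 tags in M phase with RAD21.

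Over all S-phase peaks, factor sites with and without cohesin differed by less than 3 points in how often the factor was found in M phase. HNF4A kept 14.2% of its peaks with RAD21 (12.9 to 15.5%) and 11.9% of those without (11.3 to 12.5%), a difference of 2.27 points (0.898 to 3.72). KLF5 kept 12.9% with and 10.8% without RAD21, a difference of 2.05 points (0.230 to 3.99), and MYC 12.2% and 12.7%, a difference of -0.559 points (-1.86 to 0.802). Standardised over 10 groups of the factor's own score, an analysis added after the data were seen, the sign changed for HNF4A and KLF5 and stayed negative for MYC: the differences were -2.13 points for HNF4A (-3.35 to -0.919), -0.743 for KLF5 (-2.61 to 1.12) and -2.62 for MYC (-3.87 to -1.38). Among the strongest of 3 equal groups by score, which held 78.2% of kept MYC peaks, MYC was kept at 25.5% of peaks with RAD21 and 31.2% without, a difference of -5.79 points (-8.74 to -2.75). HNF4A peaks at RAD21 without CTCF were kept in 17.7% of cases (15.8 to 19.8%), against 10.5% (8.89 to 12.2%) where both were present. KLF5 gave 16.2% and 10.2%, and MYC 13.5% and 11.2%, in the same classes. Standardised in the same way, also after the data were seen, both present minus RAD21 alone gave -1.56 points for HNF4A (-3.58 to 0.460), -4.20 for KLF5 (-7.41 to -0.986) and -1.94 for MYC (-4.08 to 0.205).

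The 3 factors bound next to one another and next to cohesin or CTCF far more often than shifted lists did, in both phases. In S phase, 23.5% of HNF4A peaks (22.8 to 24.2%), 37.7% of KLF5 peaks (36.4 to 38.9%) and 38.1% of MYC peaks (37.2 to 38.9%) overlapped a RAD21 or CTCF peak, which was 7.30, 10.2 and 10.5 times the mean of 1000 shifts. In M phase the shares were 18.7% for HNF4A (17.2 to 20.3%), 18.7% for KLF5 (17.1 to 20.4%) and 31.0% for MYC (28.9 to 33.0%), or 9.58, 9.17 and 12.2 times the shifted mean. For H3 the ratio was 1.79 in S phase and 1.61 in M phase. A MYC peak was present at 66.0% of S-phase KLF5 peaks, 46.4 times the mean of 100 shifts, and at 7.70% of M-phase KLF5 peaks, 51.6 times that mean, with an M-phase MYC list of 1974 peaks. An HNF4A peak was present at 52.8% of KLF5 peaks in S phase and at 7.27% in M phase. The comparison depends on what counts as chance. Another level came from positions drawn from the union of all 60458 listed regions, which includes the RAD21 and CTCF peaks themselves. Of draws matched to HNF4A, 57.7% met a RAD21 or CTCF peak in S phase and 49.8% in M phase. Against this level the S-phase ratios were 0.407 for HNF4A, 0.650 for KLF5 and 0.656 for MYC, and the M-phase ratios 0.376, 0.376 and 0.619. This level is high by construction, so these ratios do not show that the factors avoid RAD21 or CTCF.

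**Figure D3:**
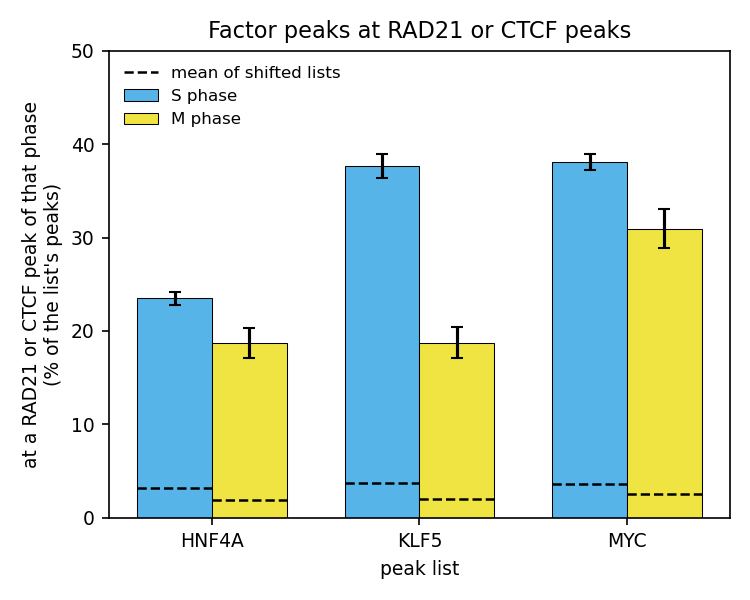
Share of HNF4A, KLF5 and MYC peaks that overlap a RAD21 or CTCF peak of the same phase (vertical axis, percent), in S phase and M phase, with 95% Clopper-Pearson intervals; dashed lines give the mean of 1000 shifted lists. All 6 bars, from 18.7% to 38.1%, stand above their dashed lines, which lie between 1.95% and 3.70%.

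Clusters of several proteins were more numerous in the S-phase lists, which were also longer. Peaks of the 5 proteins were chained where neighbours lay within 1000 bp. S phase gave 48815 clusters, of which 6071 held at least 3 of the 5 proteins and 554 held all 5; M phase gave 34451 clusters, 717 with at least 3 proteins and 2 with all 5. In S phase 66.1% of factor peaks shared a cluster with another protein, and in M phase 33.5% did. With every S-phase list limited to as many strongest peaks as in M phase, a comparison added after the data were seen, S phase had 980 clusters of at least 3 proteins and 25 of all 5, and 50.3% of factor peaks (49.0 to 51.5%) shared a cluster. Of the S-phase clusters with at least 3 proteins, 26.5% (25.4 to 27.7%) contained an M-phase peak of HNF4A, KLF5 or MYC. This share was 47.3% with the S-phase lists limited to M-phase length and 13.1% with a score of at least 100. Among those that held RAD21 or CTCF, 77.3% (76.1 to 78.5%) contained an M-phase RAD21 or CTCF peak and 23.3% (22.2 to 24.6%) an M-phase factor peak.

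More factors in a cluster went with a higher chance of an M-phase factor peak: 12.0% of S-phase clusters with 1 factor, 24.5% with 2 and 39.6% with all 3 contained one. The clusters also widened, from a median of 1231 bp with 1 factor to 2456.5 bp with 3, and held more peaks. Counted per peak, HNF4A was kept at 11.6%, 12.8% and 14.2% of its peaks with 0, 1 and 2 of the other factors, MYC at 10.5%, 12.2% and 17.8%, and KLF5 at 5.53%, 10.3% and 15.6%. At equal score only KLF5 was kept more often beside another factor, by 2.18 points (0.685 to 3.67); HNF4A differed by -2.53 points (-3.45 to -1.60) and MYC by -1.95 points (-2.94 to -0.957).

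Among S-phase clusters of all 5 proteins with an M-phase factor peak, the one with the most peaks spanned 26170 bp on chromosome 7, from 27161129 to 27187298, with 4 HNF4A, 5 KLF5, 4 MYC, 5 RAD21 and 2 CTCF peaks; in M phase 2 KLF5, 2 MYC, 2 RAD21 and 3 CTCF peaks lay within it, and no HNF4A peak. The neighbouring cluster, from 27188328 to 27213107, held the most peaks among those with no M-phase factor peak. It held 4 HNF4A, 4 KLF5 and 5 MYC peaks with 1 RAD21 and 1 CTCF peak in S phase, and 1 RAD21 and 2 CTCF peaks in M phase. On chromosome 17 from 40559642 to 40569650, 13 S-phase peaks included 5 of MYC, and M phase had 1 KLF5, 3 RAD21 and 3 CTCF peaks. A cluster of 12 peaks on chromosome 19 from 45798379 to 45806120 had 2 HNF4A, 1 KLF5 and 1 MYC peak in M phase. On chromosome 12 from 729964 to 736106, 4 RAD21 peaks stood with all other proteins in S phase, and M phase had 1 RAD21 and 1 CTCF peak.

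Few peaks of any list overlapped an H3 peak. In S phase they met 0.428% of HNF4A, 1.06% of KLF5 and 0.955% of MYC peaks, and 0.457% of RAD21 and 0.509% of CTCF peaks. In M phase the shares lay between 0.0492% for CTCF and 0.355% for MYC. Over the mean of 100 shifts, the S-phase ratios were 1.64 for HNF4A, 3.46 for KLF5 and 3.15 for MYC, and the M-phase ratios 6.06, 10 and 8.54, the latter from 4, 7 and 7 peaks. The M-phase H3 list, with an FDR of 100% for 99.8% of its peaks, was uneven along the genome: chromosomes 7 and 12 held 30.4% of its 542 peaks (26.6 to 34.5%), against 16.5% in S phase (15.3 to 17.8%). MYC had 18.1% of its M-phase peaks on these chromosomes (16.4 to 19.9%) and 11.9% in S phase (11.3 to 12.5%), and KLF5 17.4% (15.8 to 19.1%) and 13.1% (12.2 to 14.0%). HNF4A and RAD21 showed no such shift, with 12.4% and 12.5% in M phase against 12.9% and 12.8% in S phase. CTCF had 12.5% in M phase (12.1 to 12.9%) and 11.3% in S phase (10.9 to 11.6%), a small rise with intervals apart. These chromosomes were singled out after the values were seen, and others moved too: chromosome 15 held 7.56% of M-phase H3 peaks (5.48 to 10.1%) against 3.62% in S phase (3.01 to 4.31%), and 6.33% (5.30 to 7.50%) against 3.96% (3.62 to 4.33%) for MYC. Chromosome 19 fell, from 5.47% to 1.66% for H3 and from 7.35% to 3.87% for KLF5, as did chromosome 22 for both and chromosomes 16 and 17 for KLF5. Intervals of the 2 phases lay apart for 8 chromosomes of KLF5, 6 of H3, 5 of MYC and 2 of CTCF, and for 0 of HNF4A and RAD21.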

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

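The labels give a peak number, 2118, for the M-phase rabbit IgG control, a background library that none of the comparisons above uses as a measured target. It stands out because the other 3 IgG controls carry no peak number. The M-phase KLF5 list has exactly 2118 peaks, and the label of that library gives none. No peak list of the IgG control was analysed here, and the labels do not say whether the 2 libraries were exchanged, which would also touch the M-phase HNF4A, MYC, RAD21 and H3 lists called against this control. Of the M-phase KLF5 peaks, 32.3% met an S-phase KLF5 peak, against 0.524% by chance, and at most 1.09% in any of 1000 shifts, and the share of S-phase KLF5 peaks found in M phase rose from 3.71% to 43.3% between the weakest and the strongest of 10 equal groups by score. An exchange would make this list IgG called over KLF5, which should avoid KLF5 sites, so these values go against it; why the number stands at the control was not tested.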

How the results depend on the processing

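The settings with an FDR under 5%, the other choices of CTCF list, the sites with no factor, the standardised differences and the clusters of S-phase lists with as many peaks as in M phase were added after the data were seen; all others were chosen before the data were examined. Of 199 values under these settings, named regions aside, 57 stayed within the interval of the reported value (for counts, within 1.5 times). Another 130 moved and 12 changed direction. A change of direction was counted only where the interval of the reported value excluded no difference. Other changes of sign, as for MYC with and without RAD21, were counted as stayed or moved. The cause of each move was not tested unless given here. Every setting with a value for all of them but 1 left RAD21 and CTCF with higher kept shares than HNF4A, KLF5 and MYC. The exception was the limit of M-phase lists to 500 peaks. There HNF4A (34.3%) stood above RAD21 (32.2%) and CTCF (30.7%), and MYC (31.9%) stood above CTCF. Such lists of 500 peaks are too few to match 1000, and whether this limit alone changes the order was not tested. The cuts on FDR and score shorten the M-phase lists by construction, and the FDR cuts left no M-phase HNF4A peak, so HNF4A has no value there; the H3 peaks were not compared without themselves. Gene groups were not run. No list was called again at matched depth, and single libraries leave the spread between cultures unknown.

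The share of all S-phase peaks kept was, with 50% of each peak shared, 6.68% for HNF4A, 6.12% for KLF5, 9.60% for MYC, 67.5% for RAD21 and 52.9% for CTCF. With summits within 100 bp it was 8.85% for HNF4A, 5.68% for KLF5, 7.05% for MYC, 58.8% for RAD21, 61.6% for CTCF and 1.25% for H3. With a score of at least 100 it was 8.92% for HNF4A, 6.13% for KLF5, 6.65% for MYC, 68.1% for RAD21 and 61.0% for CTCF. An FDR of at most 1% gave 2.35% for KLF5, 0.368% for MYC, 39.1% for RAD21, 29.4% for CTCF and 0.405% for H3, and an FDR under 5% gave 5.16% for KLF5, 0.729% for MYC, 50.5% for RAD21, 40.1% for CTCF and 0.0447% for H3. For the strongest S-phase peaks, as many as in M phase, it was 51.4% for HNF4A, 22.8% for KLF5, 44.0% for MYC, 77.1% for RAD21, 75.6% for CTCF and 10.1% for H3.

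Of the 1000 strongest S-phase peaks, ranking by fold enrichment left 66.6% for HNF4A, 27.5% for KLF5, 49.7% for MYC, 97.6% for CTCF and 3.70% for H3. The 500 strongest gave 82.8% for HNF4A, 46% for KLF5, 71.4% for MYC, 100% for CTCF and 10.8% for H3, and the 2000 strongest 56.6% for HNF4A, 23.9% for KLF5, 43.8% for MYC and 4.10% for H3. Requiring 50% of each peak gave 38.1% for HNF4A, 16.8% for KLF5, 44.4% for MYC, 99% for RAD21, 74.7% for CTCF and 5.40% for H3, and summits within 100 bp 53.1% for HNF4A, 18.4% for KLF5, 36.3% for MYC, 95.7% for RAD21, 88.1% for CTCF and 3.10% for H3. Against the 500 strongest M-phase peaks, which are too few to match them all, it was 34.3% for HNF4A, 21.5% for KLF5, 31.9% for MYC, 32.2% for RAD21 and 30.7% for CTCF.

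RAD21 sites with CTCF were kept more often than those without under all 13 settings. The difference was 39.7 points with 50% of each peak shared, 32.9, 28.0 and 6.64 in the weakest, middle and strongest of 3 equal groups by score, 35.4 with a score of at least 100, 42.1 with the M-phase CTCF list, 55.7 with CTCF in either phase, 27.4 standardised over 10 groups, 45.3 with an FDR under 5% and 45.8 at sites with no factor.

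The difference between factor sites with and without RAD21 depended on strength. For HNF4A it was -0.426, -1.29 and 0.376 points in the 3 groups by score, -0.0605 with 50% of each peak shared, 0.844 with summits within 100 bp and -2.13 standardised. KLF5 had 0.304, -0.937 and 0.412 points in these groups and -0.743 standardised. MYC had 1.31, -1.97 and -5.79 points in the 3 groups and -2.62 standardised. Among factor sites with RAD21, the difference with minus without CTCF was -1.56 points for HNF4A, -4.20 for KLF5 and -1.94 for MYC when standardised.

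The share of HNF4A, KLF5 and MYC peaks at RAD21 or CTCF was 27.4%, 41.9% and 42.6% in S phase and 22.4%, 22.7% and 36.0% in M phase within 1000 bp, and 29.2%, 44.1% and 43.9% for the strongest S-phase peaks, as many as in M phase. Drawn from the union of listed regions, chance exceeded the observed share, with ratios of 0.407, 0.650 and 0.656 in S phase and 0.376, 0.376 and 0.619 in M phase; this level is high by construction, since 57.7% of positions drawn for HNF4A in S phase met a RAD21 or CTCF peak.

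A score of at least 100 left 1954 S-phase and 82 M-phase clusters of at least 3 proteins, 108 and 0 with all 5, and 13.1% of the former with an M-phase factor peak and 67.7% with an M-phase RAD21 or CTCF peak. A gap of 3000 bp gave 5 M-phase clusters of all 5 and 70.0% with an M-phase RAD21 or CTCF peak. With S-phase lists of as many strongest peaks as in M phase, S phase had 980 clusters of at least 3 proteins and 25 of all 5, of the former 47.3% with an M-phase factor peak and 85.8% with an M-phase RAD21 or CTCF peak. The share of factor peaks in clusters with another protein was then 50.3% in S phase; in S and M phase it was 64.7% and 31.8% with a gap of 500 bp, 70.0% and 38.7% with 3000 bp, and 49.7% and 24.2% with a score of at least 100. Of 45 values for named regions that were kept, 42 stayed and 3 changed, at the HNF4A and KLF5 sites on chromosome 1; named regions seen in 1 phase only cannot gain a match under a stricter rule and are left out of these counts.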

Other observations

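M-phase peaks with no S-phase peak of the same protein within 1000 bp differed between the proteins in what else lay there. Of 3953 such RAD21 peaks, 43.2% overlapped an S-phase CTCF peak and 35.0% an M-phase CTCF peak, and 60.8% met an S-phase peak of at least 1 of the 5 proteins. Of 4034 such CTCF peaks, 34.8% overlapped an S-phase RAD21 peak and 16.1% an S-phase MYC peak. The 478 HNF4A peaks of this kind were mostly isolated, with 6.69% at any S-phase peak of the 5 proteins, and the 444 MYC peaks met one in 20.3% of cases. The leading RAD21 example, on chromosome 1 from 241554875 to 241555842, had 54 tags at 29.49-fold and a CTCF peak in both phases. The leading CTCF example, on chromosome 2 from 179273534 to 179274763, had 72 tags at 41.21-fold and an M-phase RAD21 peak.

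The 1407 KLF5 peaks seen only in M phase made up 66.4% of their list, against 19.8% for HNF4A, 22.5% for MYC, 17.2% for RAD21 and 16.5% for CTCF. Their median score was 55.6, against 70.6 for the other M-phase KLF5 peaks. On chromosome 7 from 75195333 to 75196506, KLF5 had 31 tags at 21.69-fold with RAD21 in M phase and no listed protein in S phase. On chromosome 3 from 42166333 to 42167271, 20 KLF5 tags at 26.69-fold lay at an S-phase HNF4A peak and an M-phase RAD21 peak, and on chromosome 10 from 95220646 to 95221346, 23 tags at 22.23-fold lay at an S-phase HNF4A peak. The redundant share of tags in the M-phase KLF5 library, per its header, was 0.44, against 0.14 in S phase. The HNF4A peak of highest fold enrichment seen only in M phase, on chromosome 14 from 67110204 to 67110737, had 15 tags and an FDR of 100%.

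In the next 3 paragraphs, the tests of signal strength, of unspecific signal, of depth, of the IgG control and of joint loss at sites with no factor were chosen after the results were seen. Those of joint loss at sites with a factor, of ranks at kept peaks and of score on chromosomes 7 and 12 were written before.

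RAD21 sites without CTCF were found less often in M phase. Standardised over 10 equal groups of the S-phase score, 27.4 points (25.9 to 28.9) of the difference remained. The lower measured score at those sites thus does not account for all of it. Noise in the score was not covered, and sites of equal score can differ in true signal. Weaker true S-phase signal at sites without CTCF therefore stays open. Unspecific RAD21 signal at factor sites does not account for all of the difference. Sites with no factor gave 27.3 points (25.6 to 29.0) when standardised in the same way. A shallower M-phase RAD21 ChIP library is argued against by its filtered tags, 2.19 times those of S phase. A biological candidate explanation is that RAD21 and the bound factor leave such sites together. By definition it cannot apply to sites with no listed peak of the 3 factors, which gave the same 27.3 points. Unlisted weak binding and other factors were not measured, so joint loss with those stays open. Where CTCF was absent and a factor present, RAD21 was kept at 38.4% of the 466 sites that overlapped peaks of the same factor in both phases. It was kept at 20.9% of the 1561 others, 17.3 points apart (12.5 to 22.04) when standardised over 3 groups of score. Stronger or more accessible sites would give the same difference in both proteins, so this stays a hypothesis from single libraries.

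The factor lists were shorter in M phase, and so was that of the chromatin control H3, by a ratio of 6.07 with 1.10 times the filtered tags, so the drop is not particular to the factors. For HNF4A and MYC a shallower ChIP library is argued against, since the smaller of the ratios of filtered tags, M over S, was 1.38. For KLF5 the ratio was 0.712, so that depth stays open there. The rabbit IgG control was shallower in M phase, with 6875106 filtered tags against 10753369 in S phase. How this moved the length of the lists was not tested. Whether the M-phase rabbit IgG control hides peaks of any antibody stays open: RAD21, called against it, kept 100% of its 1000 strongest peaks, a measure already at its limit, and had an M-phase peak at 50.2% of the 6622 factor peaks with RAD21 that were not kept, where strong RAD21 signal can pass a control that weak factor signal does not. Cells outside M phase left in the nocodazole culture could supply weaker copies of the strongest S-phase peaks, and Spearman's rho between S-phase and M-phase scores, across kept peaks that are not independent replicates, was 0.351 for KLF5, 0.453 for MYC and 0.497 for HNF4A. The same rho was 0.644 for RAD21 and 0.505 for CTCF, so such cells could touch their kept peaks as well. Binding kept at the strongest sites of mitotic cells would rank alike too, so both explanations remain open. The share of cells in M phase was not analysed here.

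The M-phase H3 and MYC lists held more peaks on chromosomes 7 and 12 than the S-phase lists; so did KLF5, with 17.4% against 13.1%, and CTCF, with 12.5% against 11.3%, and chromosome 15 rose too, to 7.56% for H3 and 6.33% for MYC, but only 7 and 12 in H3 and MYC were tested. Of the M-phase H3 peaks, 99.8% had an FDR of 100%; HNF4A, with 78.8%, did not rise (12.4% against 12.9%), nor did RAD21 (12.5% against 12.8%), and these lists go against a lift of weak signal in every library. Extra copies of these chromosomes could lift weak signal over the threshold, which would put the excess among the weakest peaks. The share on these chromosomes in the weakest minus the strongest of 3 equal groups by score was -2.21 points for H3 (-11.5 to 7.18) and 1.98 points for MYC (-2.26 to 6.21). Both intervals include 0, so with 542 and 1974 peaks this explanation cannot be told apart from others, and no biological explanation was tested.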
